A study of Drosophila melanogaster with 4 samples.

How the data were processed

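Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was applied to nuclei of wild-type Oregon-R Drosophila melanogaster at the third larval instar, with an antibody against H3K9acS10P, histone H3 that carries an acetylated lysine and a phosphorylated serine next to it. The labels describe 4 samples: 2 ChIP samples (replicates 1 and 2) and 2 input samples, each serving as the background of the ChIP sample with its number. Per the labels' protocols, tissue was homogenised and fixed with formaldehyde, nuclei were lysed and sonicated, and chromatin was incubated with the antibody and collected on beads. The labels do not say whether the replicates came from separate cultures, so differences between them measure only the spread between these samples, which may be technical. The sex of the larvae is not given in the labels.

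The analysis started from 3 lists of enriched regions, called clusters here: 1 list for each ChIP sample, called per sample, and 1 list for the pair, named in the deposited file as a replicate set and called the combined list here. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. Coordinates are on FlyBase release 5, per the file headers, and the chromosome lengths used here were taken from the same headers. The cluster caller, its threshold, the way the replicates were combined and the treatment of reads that map to repeats are not given in the sources used here. Each cluster in the deposited lists has a start, an end and a score given by the authors. How this score was computed is not given in the sources used here. No read totals were analysed here, so the depth of each library is unknown and the 95% Wilson intervals given below cover counting of clusters only. The lists hold only regions that passed the authors' threshold, and input values were not used here, so no background level accompanies the clusters.

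The scale of the deposited score is not named by the authors. Among score values that occurred at least 3 times within a list, 36.5% (combined), 44.6% (replicate 1) and 50.7% (replicate 2) differed from the commonest score by the log2 of a ratio of whole numbers with a denominator up to 60, within a relative tolerance of 1.0e-07. With natural or decimal logarithms the share was at most 1.79% in any list. Scores are therefore read here as log2 ratios of read counts up to a constant, and they were used to rank, filter and describe clusters within 1 list. Between lists, scores were set side by side only for overlapping clusters, as a correlation and for the named clusters, and a difference in score between lists is not read as a change. A score is called a ratio of small whole numbers where its ratio to the commonest score of its list, on the log2 scale, is a fraction with a denominator up to 100, within the same tolerance. All start and end positions of the combined list were even numbers (100%), against 24.9% and 25.8% of clusters with both positions even in the replicate lists. The shortest cluster was 1001 bp in the combined list and 1301 bp in both replicate lists. Whether the lists were made with different width limits is not known. Regions typed as depleted, 1 in the combined list and 1 in replicate 2, were left out of all counts.

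Clusters were called met when they overlapped a cluster of another list by at least 1 bp, and the counts were the same with bedtools 2.31.1. Chance overlap was estimated from 1000 circular shifts of the second list within each chromosome, one-sided. Coverage is the percentage of a sequence's full length inside clusters, with gaps and repeats in the sequence left in. The X was compared with the 4 large autosomal arms (2L, 2R, 3L and 3R) over complete 1 Mb bins with a two-sided permutation test of 100000 resamples, and the 9 tests of this family (3 measures in 3 lists) were adjusted by the Benjamini-Hochberg method. Neighbouring bins are not independent replicates, so an added test moved the X label along the ordered bins through all 117 positions, and its smallest possible p is 0.00855. The circular-shift overlaps, the X coverage test, the coverage per sequence, the score concordance and the rule for named regions were fixed before the data were examined. The score scale, the X score and width tests (6 of the 9 in the family), the moved X label, the 1 Mb profiles, the arm ends, the clusters of at least 10 kb, the split of overlap by score and by sequence and the stretches without clusters were added after the lists had been read. The rule names the 10 highest-scoring and the 5 widest combined clusters met by both replicate lists, and the 5 highest-scoring clusters of each replicate list not met by the other. All computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

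The overlap script was tested on simulated data made from the 6080 replicate 1 clusters. With no planted overlap, 0 of 10 simulated lists gave a p under the threshold of 0.05, and with 50% or 80% of clusters planted all 10 did. The measured share then lay 0.65 and 0.405 percentage points above the planted share plus chance hits. The bin test gave a p under 0.05 in 2 of 50 simulated sets of 117 normally distributed, independent bins with no X difference and in 50 of 50 with an X to autosome ratio of 1.3. Relative to their mean, the simulated bins varied less than the bins of the lists, and no smaller X difference was simulated. The simulation therefore does not show how well a small X difference would be found.

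Planned tests at transcription start sites, along gene bodies and for 21 gene lists were not run. The only gene table used here is on genome release 6, whose coordinates differ from release 5, so no cluster was assigned to a gene. Alternatives tried were the 50% of each list with the higher score, a minimum width of 500 bp, an overlap of 50% of the shorter cluster or of both, base pairs in place of clusters, each replicate list alone, combined clusters met by both replicates, 500 kb bins, clusters per Mb, Pearson correlation and one-to-one overlaps for the scores. Alternatives added after the lists had been read were the 5 large arms alone, combined clusters at least as wide as the shortest replicate cluster, the moved X label and all settings of the X score test.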

Results

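The ChIP-seq lists hold 6080 H3K9acS10P clusters in replicate 1, 7282 in replicate 2 and 9877 in the combined list. The mean over the 2 replicates was 6681 ± 850 clusters (SD, n = 2). Median cluster width was 2473 bp in replicate 1, 2337 bp in replicate 2 and 2207 bp in the combined list. The widest cluster of the combined list spanned 29.0 kb. Clusters covered 12.97% of the 13 chromosome arms and scaffolds in replicate 1, 15.5% in replicate 2 and 20.3% in the combined list. Wider clusters had higher scores in every list, with a Spearman rho across clusters of 0.67 in replicate 1, 0.69 in replicate 2 and 0.55 in the combined list. Clusters are not independent replicates, so these correlations describe the lists and carry no p.

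The first comparison asked where in the genome the mark was called. The 5 large arms (X, 2L, 2R, 3L and 3R), which hold most euchromatic genes, were covered at 16.1% ± 1.77 (SD, n = 2) of their length. Arm 2R was the most covered in both replicates, at 17.4% in replicate 1 and 20.7% in replicate 2. The least covered large arm was 2L, at 13.2% and 14.5%. Chromosome 4, a small chromosome known to be rich in repeats and in HP1-bound chromatin, was covered at 9.65% ± 1.17 (SD, n = 2), with 54 clusters in replicate 1 and 49 in replicate 2. The 6 heterochromatin scaffolds (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet) were covered at 3.72% ± 2.28 (SD, n = 2). Coverage of U, the collection of sequence not placed on a chromosome, was 2.48% ± 2.13 (SD, n = 2). The combined list covered more of them, at 9.85% of the heterochromatin scaffolds, 8.68% of U and 22.1% of the large arms. In both replicates the scaffolds and U together were covered less densely than the large arms, at 0.102 of the arm value in replicate 1 and 0.267 in replicate 2. No cluster was listed on Uextra in any of the 3 lists. With 1 sequence of most kinds and 2 replicates, these coverages are values without a test. The lengths include gaps and repeats where reads may not be placed, so low coverage cannot be read as a low level of the mark.

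**Figure D1:**
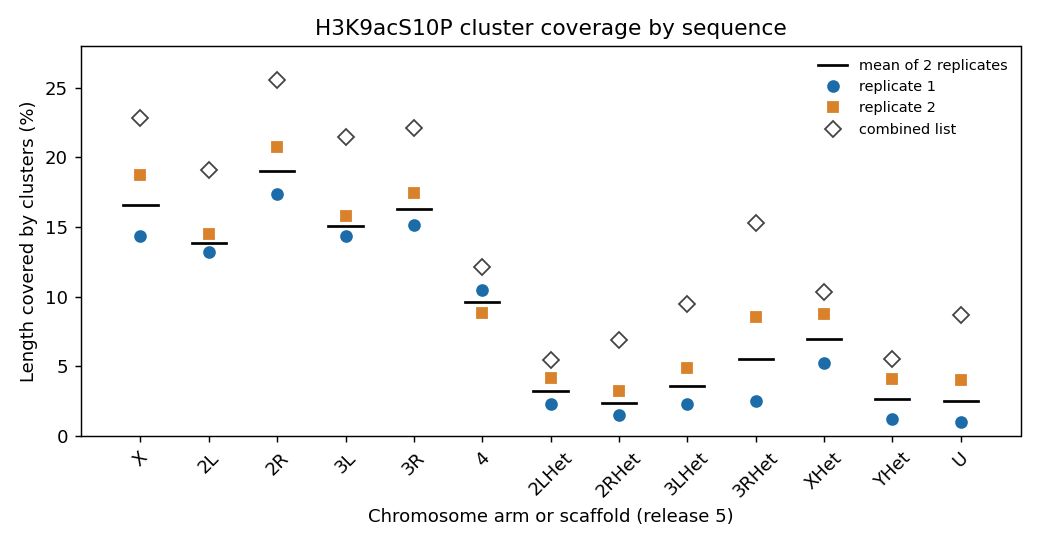
Percentage of each release 5 chromosome arm or scaffold (x axis) covered by H3K9acS10P clusters (y axis). Filled points are the 2 replicates, the bar is their mean and the open diamond is the combined list. The 5 large arms lie between 13.2% and 20.7% in the replicates, and U at 0.98% and 3.99%.

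The scaffolds separated the replicates more than the arms did. Replicate 2 covered 1.17 times as much of the large arms as replicate 1, with a range of 1.10 (3L) to 1.31 (X) over the 5 arms. On the heterochromatin scaffolds the ratio was 2.53, and on U it was 4.07. Chromosome 4 went the other way, at 0.842. Scaffold 3RHet, the most covered of the 6 in the combined list at 15.3%, was covered at 2.54% in replicate 1 and 8.57% in replicate 2. YHet, sequence of the Y chromosome, held 2 clusters in replicate 1, 7 in replicate 2 and 11 in the combined list.

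Within the large arms, coverage varied by position. The end of the arm next to the centromere was sparsely covered on 4 of the 5 arms, with the same limit on how low coverage can be read. In the 1 Mb of 3L nearest the centromere, 1.95% (replicate 1) and 5.37% (replicate 2) of the length was covered, against 14.5% and 15.8% in the middle of the arm. The corresponding end of 2R was covered at 4.87% and 7.35%, against 18.0% and 21.2% in its middle. The proximal 1 Mb of the X was covered at 5.08% and 7.40%, and that of 2L at 5.95% and 7.26%. On 3R the proximal 1 Mb was covered at 18.6% and 21.7%, above its middle at 15.0% and 17.3%. The telomeric 1 Mb of 2L was covered at 23.2% and 25.1%, against 13.05% and 14.3% in the middle, and that of 3L at 24.0% and 26.2%. The telomeric ends of the other arms were nearer to their middles. That of 2R was covered at 18.4% and 24.5%, that of the X at 15.0% and 17.7% (middle 14.8% and 19.4%), and that of 3R at 15.1% and 16.3%, so on the X and 3R it was below the middle in replicate 2.

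Over 117 bins of 1 Mb, the 2 replicates ranked regions alike, with a Pearson r of 0.93 and a Spearman rho of 0.94 across bins. The most covered bin of the combined list was X from 1000001 to 2000000, at 41.8% (23.7% in replicate 1 and 37.8% in replicate 2). Next came 2R from 3000001 to 4000000, at 38.9% (24.3% and 33.3%). The least covered bin was 2L from 17000001 to 18000000, at 5.62% (3.26% and 3.28%). A second interior stretch of the same arm, from 15000001 to 16000000, was covered at 8.31% (5.75% and 5.92%). Bins are neighbours on 5 arms and not independent replicates.

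**Figure D2:**
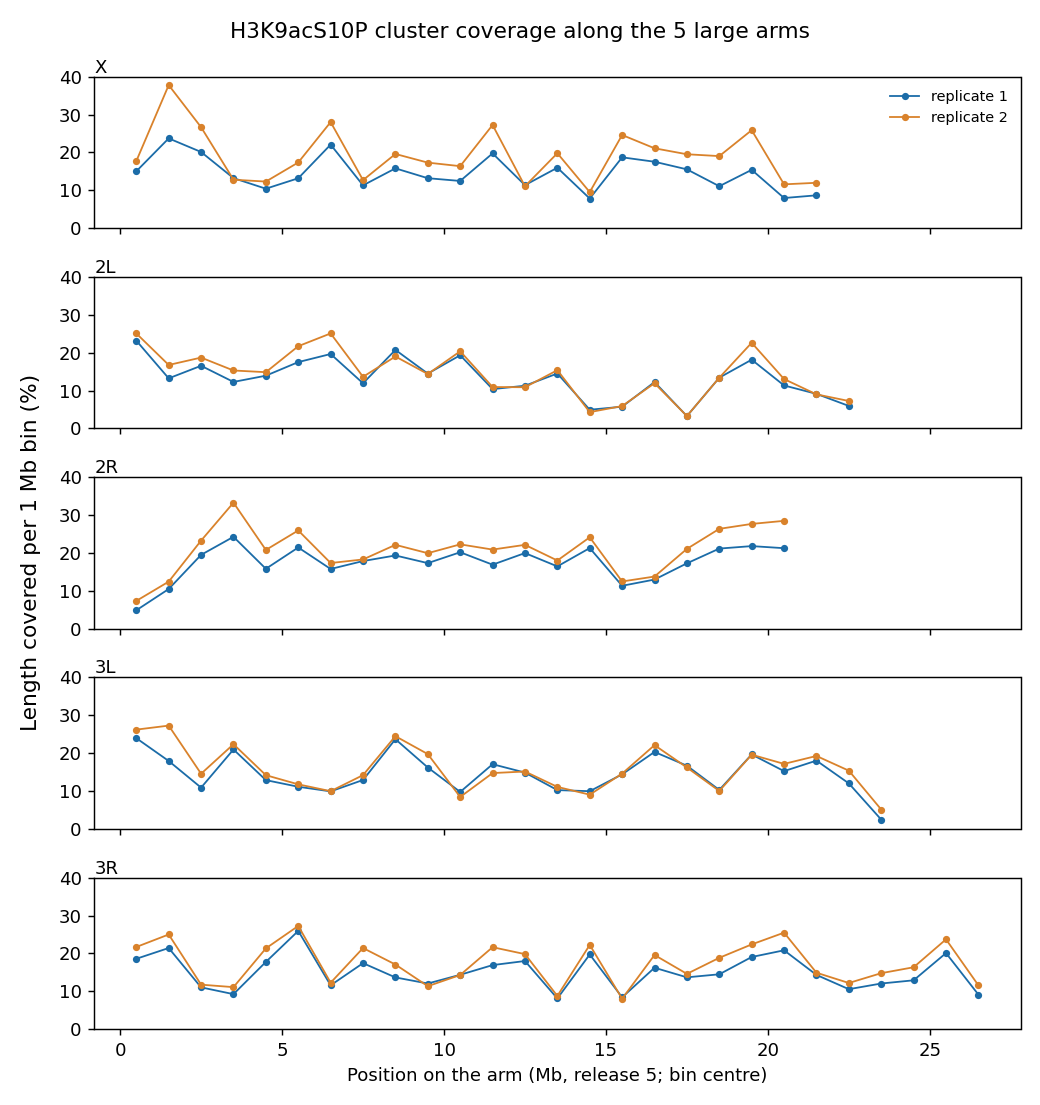
Percentage of each complete 1 Mb bin covered by clusters (y axis) against the position of the bin on the arm in Mb of release 5 (x axis), one panel per large arm and one line per replicate. The lines run in parallel (Pearson r of 0.93 across the 117 bins), with low coverage at the centromeric ends of X, 2L, 2R and 3L and near 17.5 Mb on 2L.

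The second comparison set the X against the autosomes, because phosphorylation of this H3 serine by the kinase JIL-1 is known to be enriched on the male X of flies. The X was not covered more than the autosomal arms by more than the spread between bins. Coverage of the X was 1.04 times that of the autosomal arms in the combined list (permutation p = 0.502, Benjamini-Hochberg adjusted p = 0.611). The ratio was 0.957 in replicate 1 and 1.10 in replicate 2, so the direction differed between the replicates (1.03 ± 0.103, SD, n = 2). In the 50% of the combined list with the higher score, X coverage was 1.20 times the autosomal value (permutation p = 0.0197), a selection on a score that was itself higher on the X. Density of all combined clusters was 72.3 per Mb on the X and 74.7 per Mb on the autosomal arms.

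Clusters on the X scored higher than those on the autosomal arms in all 3 lists. The median score per 1 Mb bin averaged 0.88 ± 0.13 (SD over 22 bins) on the X in replicate 1, against 0.74 ± 0.14 over 95 autosomal bins. This difference of 0.15 log2 units, 1.11-fold on the linear scale, had a permutation p of 7.0e-05 (adjusted 3.1e-04). In replicate 2 the X averaged 0.75 and the autosomes 0.65, a difference of 0.10 log2 units with a permutation p of 3.0e-05 (adjusted 2.7e-04). The combined list gave 0.04 log2 units with a permutation p of 0.00761 (adjusted 0.0228). Moving the X label along the ordered bins gave a permutation p of 0.00855 in each replicate, the smallest that 117 positions allow, and 0.0342 in the combined list. The moved labels overlap each other and there is 1 X, so no p here measures the spread between chromosomes. By arm, the X had the highest mean in each list, but in the combined list it was 0.473 against 0.454 on 2R and 0.448 on 3R. Chromosome 4, left out of this comparison, had a higher median cluster score than the X in the combined list (0.657 against 0.463). The same held in replicate 1 (0.960 against 0.881), but not in replicate 2 (0.590 against 0.735). Scores on the X were also more often ratios of small whole numbers than autosomal scores of the same size, at 14.6% against 8.53% in replicate 1 and 18.6% against 12.97% in replicate 2.

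**Figure D3:**
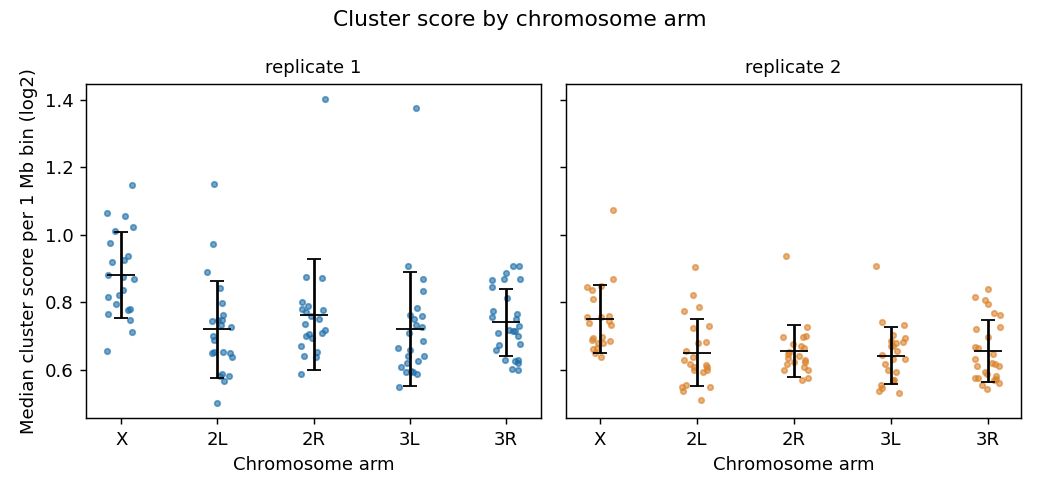
Median cluster score per 1 Mb bin (y axis, log2 units of the authors' score) for each large arm (x axis) in the 2 replicates. Points are bins, and black marks show the mean and SD over the bins of an arm; the X mean is 0.88 in replicate 1 and 0.75 in replicate 2, above the mean of each autosomal arm in both.

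Of 177 combined clusters of at least 10 kb, 54 lay on the X, which is 30.5% of them, while the X makes up 18.8% of the length of the large arms. In the replicate lists the X held 16 of 54 and 30 of 92 such clusters. None of the clusters of this width lay on chromosome 4, the heterochromatin scaffolds or U. Of the 5 widest clusters met by both replicates, 4 were on the X. They ran from 1956664 to 1985682 (29.0 kb, combined score 1.11), from 6868370 to 6897354 (29.0 kb, 0.81), from 1751004 to 1776242 (25.2 kb, 1.65) and from 1499726 to 1522334 (22.6 kb, 1.15). The other was on 3L from 20923644 to 20945184 (21.5 kb, 0.57). The replicates split the X regions among these differently: the cluster from 6868370 met 2 clusters in replicate 1 and 7 in replicate 2. The 3L cluster met 3 in each replicate. Median width per bin on the X and the autosomal arms did not differ beyond the spread between bins after adjustment in any list (adjusted p = 0.177 in replicate 1, 0.0678 in replicate 2 and 0.611 in the combined list, permutation tests).

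The third comparison measured how far the replicates called the same regions. Of the 6080 replicate 1 clusters, 5222 (85.9%, 95% Wilson interval 85.0 to 86.7) met a replicate 2 cluster, against a mean of 29.1% over 1000 circular shifts. Of the 7282 replicate 2 clusters, 5199 (71.4%, interval 70.3 to 72.4) met a replicate 1 cluster, against 24.7%. Both shares exceeded every shift, which gives a one-sided permutation p of 1.0e-03, the smallest that 1000 shifts allow. In base pairs, the overlap was 61.4% of the union of both lists, against 8.53% over shifts. Scores of overlapping clusters had a Spearman rho of 0.77 across 5583 overlapping pairs, which are not independent replicates. On the large arms rho was 0.78 over 5452 pairs, and on the heterochromatin scaffolds and U it was 0.55 over 87 pairs.

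Sharing differed by score. On the large arms, the share of replicate 1 clusters that met replicate 2 was 63.2%, 84.0%, 99.5% and 99.9% from the lowest to the highest score quartile. For replicate 2 it was 58.5%, 54%, 85.9% and 99.7%, so the lowest share was in the second quartile. Width also differed between the quartiles, with a median of 1770 bp in the lowest and 3264 bp in the highest in replicate 1. In base pairs, the replicates shared the large arms (Jaccard 63.3%) and chromosome 4 (64.7%) to a similar extent. In clusters met they differed, and in opposite directions. On chromosome 4, 77.8% of replicate 1 and 89.8% of replicate 2 clusters met the other list, against 86.6% and 74.5% on the large arms. The next values are again Jaccard shares. The heterochromatin scaffolds reached 21.2% and U 11.3%. Replicate 2 covered 2.53 and 4.07 times as much of them as replicate 1, which by itself limits these shares. Chance overlap was not estimated for each kind of sequence. On U, 28 of 55 replicate 1 clusters (50.9%, 95% Wilson interval 38.1 to 63.6) and 28 of 200 replicate 2 clusters (14%, interval 9.87 to 19.5) met the other list.

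**Figure D4:**
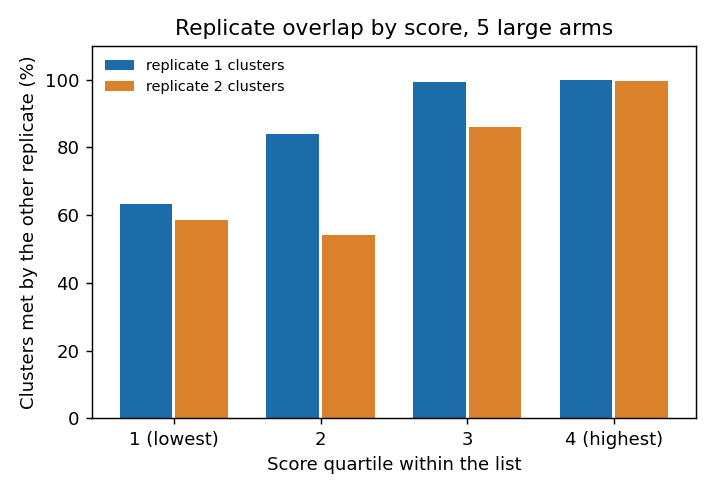
Percentage of clusters on the 5 large arms that met a cluster of the other replicate (y axis, bars from 0), by score quartile within each list (x axis). The share is 63.2% and 58.5% in the lowest quartile and 99.9% and 99.7% in the highest, with the minimum of replicate 2 (54%) in the second.

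The 10 highest-scoring combined clusters met by both replicates were spread over 6 sequences. The highest lay on U from 5540920 to 5543330, with a score of 3.11 (3.20 in replicate 1 and 2.96 in replicate 2). On chromosome 4, the cluster from 86050 to 88782 scored 2.49 (2.64 and 2.36). Arm 2L held 2 of the 10, from 19006740 to 19010186 with a score of 2.43 and from 8040256 to 8044950 with 2.39. Arm 3R held 1, from 17121442 to 17124696, which scored 2.37. On 2R there were 4: from 12456664 to 12459650 (2.37), from 7776360 to 7783296 (2.28), from 20788272 to 20792832 (2.28) and from 10102312 to 10105046 (2.25). The X cluster from 11252346 to 11254750 scored 2.24, with 1.96 in replicate 1 and 2.07 in replicate 2. Each of the 10 met exactly 1 cluster in each replicate list. Of the 100 highest-scoring clusters of this kind, 18 were on the X, 78 on the autosomal arms, 1 on chromosome 4, 1 on YHet and 2 on U.

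Clusters of one replicate that did not meet the other numbered 858 in replicate 1 and 2083 in replicate 2. The highest-scoring of them lay mostly on U. In replicate 1 these were U from 3137685 to 3138998 and from 5454291 to 5455595 (both 3.69), X from 21601513 to 21602863 (3.39), and U from 6438009 to 6439956 (2.63) and from 3171398 to 3172911 (2.60). In replicate 2 they were U from 7549914 to 7552120 (4.17), from 6645567 to 6647915 and from 6778542 to 6780225 (both 3.71) and from 7481266 to 7482627 (3.46), and 2RHet from 1995925 to 1997584 (3.46). Some of these met no combined cluster either: X from 21601513 and U from 3171398 in replicate 1, and U from 6778542 and from 7481266 in replicate 2.

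The last comparison asked which clusters of the combined list each replicate also gave. The combined list met 6047 of the 6080 replicate 1 clusters (99.5%) and 6866 of the 7282 replicate 2 clusters (94.3%). In the other direction, 56.7% of combined clusters met replicate 1 and 65.7% met replicate 2, against 23.5% and 27.1% over circular shifts (one-sided permutation p = 1.0e-03 each, the smallest possible). The combined list belongs to the same 2 ChIP samples, so overlap above the shifts was set in advance. This p is therefore no evidence of agreement. On the large arms, 4689 of 8834 combined clusters (53.1%) met both replicates and 2076 (23.5%) met neither. On U, 29 of 489 (5.93%) met both and 285 (58.3%) met neither. Combined clusters on the large arms met by both replicates had a median width of 3361 bp and a median score of 0.79. Those met by neither had a median width of 1239 bp and a median score of 0.34. The median score was as low in arm clusters met by replicate 1 alone (0.32) or by replicate 2 alone (0.35). On the heterochromatin scaffolds the median score was 0.52 in clusters met by neither and 0.81 in those met by both. On U the clusters met by neither had a median score of 1.05, and those met by both had 1.03. Among combined clusters at least as wide as the shortest replicate cluster, 69.1% met replicate 1 and 77.6% met replicate 2.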

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

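The settings that used the 5 arms only, combined clusters of a minimum width, the score test on the X or a moved X label were chosen after the data were seen. The shares of clusters met between lists stayed above their circular-shift values under every alternative run (permutation p = 0.0099, the smallest that the 100 shifts used there allow). For the combined list this was set in advance, since it belongs to the same 2 ChIP samples. At a reciprocal overlap of 50% they were 72.5% of replicate 1 and 60.5% of replicate 2 clusters, and 51.3% and 58.4% of combined clusters met by replicates 1 and 2. A minimum width of 500 bp removed nothing, since the shortest cluster had 1001 bp. Score concordance was 0.74 as Pearson r and 0.84 as Spearman rho over one-to-one overlaps. The Pearson r was taken on the log2 of the deposited score, which is itself read here as log2. The X to autosome coverage ratio was 1.20 (permutation p = 0.0197) in the higher-scoring 50%, 0.968 in clusters per Mb, and 0.957 to 1.10 with one replicate left out, the lower value being replicate 1 alone; the cause was not tested. The X score difference was reversed in direction, at -0.017 (permutation p = 0.529), in the higher-scoring 50% of the combined list. This setting selects on the score it then compares and so does not test that difference. Coverage of chromosome 4 was 9.39% in the higher-scoring 50%, 8.70% with combined clusters met by both, and 8.83% to 10.5% with one replicate left out, against 12.1% in the combined list. Heterochromatin scaffold coverage was 2.03% with clusters met by both and 2.11% to 5.33% with one replicate left out, against 9.85% in the combined list. The same settings gave 1.05% and 0.98% to 3.99% on U, against 8.68%; the cause was not tested. Median width and median score of the higher-scoring 50% were 3135 bp and 0.867, which follows from the choice by score, since wider clusters score higher. Depth is unknown, so the lists cannot say whether a region met in 1 list is absent from the other or lies under its threshold. The planned start-site, gene-body and gene-list tests and the X ratio per start site were not run, because no gene table on release 5 was used here. No paired analysis was possible because the input samples that share the numbers of the ChIP samples have no values in the lists analysed here.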

Other observations

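All patterns below were found in the data they were tested on. The tests of width and weak score of combined clusters, of extra calls in replicate 2, of the matched share in replicate 1, of tied scores at the same score mix, of the lowest X scores and of the stretches without clusters were chosen only after the result was seen. Large parts of the euchromatic arms held no cluster in any list. There were 142 such stretches of at least 100 kb, 21.5 Mb in all or 18.0% of the 5 large arms, with 40 on 3R, 35 on the X, 31 on 2L, 22 on 3L and 14 on 2R. The longest ran for 478 kb on 2L from 15771099 to 16249329, followed by 353 kb on 2L from 16911245 to 17264381 and 333 kb on 3R from 23814629 to 24148002. Counted in the combined list alone, without regard to the replicate lists, there were 143 stretches of this length. Uniform random placement of the same clusters gave a mean of 0.789 and at most 5 over 1000 draws (one-sided permutation p = 1.0e-03, the smallest these draws can give). Uniform placement leaves almost no such stretch, so this p says only that the clusters were not placed uniformly. Gaps and repeats in the sequence were not removed. Genes tend to lie in groups, and which genes lie in these stretches was not analysed here.

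Clusters on heterochromatin scaffolds and U were shared less between replicates than clusters on the arms. Extra calling in replicate 2 by 1 common factor everywhere is argued against. The ratio of covered length was 3.05 on the scaffolds and U and 1.10 to 1.31 on the arms. So unequal a covered length by itself limits the share in base pairs and the share of replicate 2 clusters met. Depth and threshold are unknown, so a difference in calling with a larger effect on the scaffolds and U stays open. Low score or short width was examined by matching. In replicate 2, 27.6% of 286 clusters met the other list, against a central 95% of 60.5% to 68.5% for arm clusters matched on both. Replicate 1 listed 147 clusters on the scaffolds and U against 431 in replicate 2, which by itself limits this share. The values therefore cannot decide whether low score or short width is the whole cause in replicate 2. Another 145 clusters were left out because their score and width class held under 10 arm clusters. In replicate 1 the same explanation cannot be told apart, because the answer depends on that minimum: a first version without it gave 59.2% of 147 clusters, at the bound of 59.2% to 69.4%, and the minimum, introduced after that value was seen, gave 64.8% of 125 against 69.6% to 81.6% (without it, replicate 2 gave 21.3% against 45.8% to 51.7%). It also stays open that the calls on the scaffolds and U may rest on few reads. Scores that were ratios of small whole numbers (denominator up to 100, relative tolerance 1.0e-07) made up 40.8% of scaffold and U clusters in replicate 1 and 55.5% in replicate 2. On the arms they made up 10.6% and 14.6%, with no matching on score. Tied scores, a second measure of few reads, were 1.83 times as frequent there as on the arms in replicate 2 and missed the factor of 3 set beforehand, a bound that ignored score (ties in the lowest and highest score quartile of replicate 2 were 31.8% and 2.24% on the arms, and 34.6% and 35.6% on the scaffolds and U); at the same score mix ties were 23.1% against 7.85% on the arms in replicate 1 and 36.9% against 12.7% in replicate 2, a ratio of 2.91 in replicate 2 that goes with few reads but is still short of 3, and no biological explanation was tested.

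Clusters on the X scored higher than those on the autosomal arms, and the 5 highest X bins are argued against as the whole cause. Without them the difference was 0.09 log2 units in replicate 1 (permutation p = 0.0118) and 0.0566 in replicate 2 (permutation p = 0.0115). These p-values treat neighbouring bins as independent, and the X label was not moved along the bins in this setting. Fewer weak calls on the X cannot be told apart from a higher level, because the replicates differ: clusters at or above the autosomal upper quartile were 1.37 times as dense on the X in replicate 1 (permutation p = 6.9e-04) and 1.13 times in replicate 2 (permutation p = 0.19). A higher score needed for a call on the X cannot be told apart from a higher level either: the 5th percentile of the score lay 0.09 (95% bootstrap interval 0.07 to 0.11) and 0.0599 (0.04 to 0.08) log2 units higher there in replicates 1 and 2, but a plain upward shift, such as the differences of 0.15 and 0.10 in the bin medians, would raise it too. Fewer reads behind X scores are a candidate explanation, since ratios of small whole numbers were 1.71 and 1.43 times as frequent as on autosomes at the same score mix. A single X per cell in male larvae could give fewer reads, and enrichment of the mark on the X stays open too, but the labels give no sex and neither was tested.

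Of the combined clusters, 26.3% met neither replicate list, and whether a limit on cluster width is the cause stays open. At least as wide as the shortest replicate cluster were 42.3% of those on the arms, 39.9% on the heterochromatin scaffolds and 43.5% on U. These are widths in the combined list. The width that the same regions would have in a replicate list is unknown, so the shares cannot decide the question. It also stays open whether the clusters met by neither list on the arms and the heterochromatin scaffolds are weak regions that pass only when replicates are combined. Of these, 98.5% of 2076 and 81.1% of 233 scored below the median of arm clusters met by both. So did 99.7% and 86.1% of those met by a single replicate list, so a low score does not set them apart. On U most of them did not score low: 36.8% of 285 scored below that median and 180 did not. A ratio of few reads can be high, so these scores cannot decide whether the regions on U are weakly supported. No biological explanation was tested.

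The region typed as depleted lay on 3L from 12734162 to 12735984 in the combined list and from 12734458 to 12735958 in replicate 2, and replicate 1 listed none.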
